A study of Arabidopsis thaliana with 9 samples.

How the data were processed

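RNA from shoots of Arabidopsis plants exposed to high light for 0, 20 or 60 s was sequenced by the authors, with 3 pools of at least 30 plants per exposure per the labels' protocols. Growth was at 23 °C and the exposure at 21 °C, per the labels. The authors deposited FPKM values, that is fragments scaled by transcript length and by the number of mapped fragments, as 1 value per gene and exposure. The submitters' processing notes name TopHat (a spliced aligner), Bowtie (the aligner it calls) and Cufflinks (which estimates FPKM), and the TAIR9 build. Tool versions, the way the 3 pools of an exposure were combined, strand handling, the normalization between exposures and any masking of genes are not given in the sources used here. An estimator of this kind divides reads that fit several gene copies, and it can fail on very short or very abundant genes. Values of gene families and overlapping genes are therefore uncertain, and an exact 0 is described only as listed at 0.

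The design fixed before the data were examined planned limma on log2(FPKM + 1) of 9 samples. The table has 1 value per exposure, so no test was made, and the rule written beforehand for that case was used. It takes log2((x + 1)/(y + 1)) with a pseudocount of 1 FPKM as a value without error, for genes with a mean of at least 5 FPKM over the 3 exposures. This scale understates the differences of low genes. A count at 2-fold describes the table and is not a count of changed genes. The 3 columns were matched to the exposures by their names, and 0 columns were left unmapped.

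Genes were named by a rule written beforehand, namely the 10 highest and 10 lowest ratios per comparison and the 2 highest and 2 lowest members of each list. On all genes that rule picked mainly short features listed at 0. It was therefore applied again to protein-coding genes above 0 FPKM at every exposure with a locus of at least 300 bp overlapping no other listed gene, a restriction chosen after the values were seen. Genes named outside the rule are marked as such, and members of the families and held-out lists of the closing section were also chosen after the values of other genes had been seen.

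The 17 gene lists were fixed beforehand, 16 of them by locus code. Of 270 list entries, 261 matched the reference symbol or a synonym, and the other 9 were kept by locus code. They cover scavenging of reactive oxygen species, rapid stress transcription factors, touch and calcium, heat shock, abscisic acid, jasmonate, salicylic acid and defence, light signalling and flavonoids, nuclear photosynthesis genes, the clock, auxin, reference genes, markers of root, flower, epidermis and guard cells, and vasculature, and cytosolic ribosomal proteins. The last list was taken from reference descriptions, matched 19 genes, and holds mostly acidic stalk proteins. The median ratio of each list with at least 3 tested members was placed among 10000 random lists of equal size matched on mean FPKM in 20 bins, with seed 7. A list was called outside when it lay below the 2.5th or above the 97.5th percentile.

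Symbols, gene types, exonic length and GC content came from the RefSeq annotation of assembly TAIR10.1, which matched 32690 of 33473 identifiers (97.7%). Coordinates are those of the deposited table, shifted by 1 to count from 1, because 8829 of 12238 genes with the same end as the reference had the same start after adding 1 and 25 had it as printed. Ratios between columns for 1430 genes above 0 and under 0.2 FPKM at every exposure did not gather on a single step. Some gathering was present. In log2 bins 0.004 wide, the fullest bin held 20 (20 s against 0 s), 12 (60 s against 0 s) and 13 genes (60 s against 20 s). The mean per bin was 0.94 to 0.95. Steps within a column were not checked, so whole reads were not recovered and the depth stayed unknown. Across the 13946 genes the middle 95% of log2 ratios ran from -0.29 to 0.49 at 20 s and from -0.32 to 0.49 at 60 s against 0 s.

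The ratio step was run on simulated data for 13915 genes to check that the code computes what was intended. At the error assumed there, a 2-fold limit takes in 3-fold differences and leaves out 1.5-fold ones by construction, so the run says nothing about performance at the real error, which is unknown. Sharing between the 2 comparisons with 0 s was set beside 100 simulations of unchanged groups, whose error came from the spread of the 60 s against 20 s ratios. Alternatives were other pseudocounts, minimum levels, median centring, quantile normalization, a 1.5-fold limit and the restricted set. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.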

Results

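RNA was sequenced from shoots of Arabidopsis thaliana, accession Col-0, at the age of 21 days. The plants had been raised under constant low light of 50 µmol m-2 s-1 and were then placed under 1000 µmol m-2 s-1 for 0, 20 or 60 s before the pots were dipped in liquid nitrogen. The labels describe 3 independent pools of plants for each exposure, 9 samples in all. The table analysed here holds 1 FPKM value (fragments scaled by transcript length and by the number of mapped fragments) per gene and exposure, with no value for the single pools and no error. No difference given below therefore has a replicate check, no test was possible, and the words higher and lower describe the deposited values only. The FPKM values summed to 817000 at 0 s, 829701 at 20 s and 858218 at 60 s over 33473 listed genes, of which 22997, 22859 and 22732 were above 0. For the light-harvesting gene LHCB1.3 alone, listed at 0, 15970 and 18990 FPKM, the rise from 0 s to 20 s exceeds that of the sum. This gene makes up only part of the rise of the sum from 0 s or from 20 s to 60 s. The number of reads behind the deposited values is unknown.

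The first comparison asked which transcripts differed after 20 s of high light. PHI-1 (AT1G35140), a member of the EXORDIUM family of cell wall associated proteins, had 1.64 FPKM at 0 s and 20.5 FPKM at 20 s, an 8.12-fold difference on the scale of FPKM + 1 that is used for every fold given here. NATA1 (AT2G39030), an N-acetyltransferase, was 5.97-fold higher (0.941 against 10.6 FPKM), and DREB26 (AT1G21910), a transcription factor of the AP2/ERF class, was 5.42-fold higher (1.97 against 15.1 FPKM). TCH4 (AT5G57560), a xyloglucan endotransglucosylase/hydrolase first known as a touch-induced gene, was higher by 2.07 on the log2 scale (29.0 against 125 FPKM), and EXO (AT4G08950), the founding member of the EXORDIUM family, was 3.13-fold higher (34.9 against 111 FPKM). DIN10 (AT5G20250), of the raffinose synthase family, was 3.11-fold higher at 139 FPKM, and ASN1 (AT3G47340), the dark-inducible asparagine synthetase, was 2.81-fold higher at 13.5 FPKM.

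The remaining genes among the 10 with the highest ratios were AT2G20670 (22.8 against 80.9 FPKM), AT5G19120, annotated as an aspartyl protease (21.3 against 70.9 FPKM), and AT4G36850, annotated as a PQ-loop membrane protein (3.69 against 13.9 FPKM). Lower values were fewer and smaller. AT3G01345 went from 17.5 to 5.31 FPKM (2.93-fold lower), BBX30 (AT4G15248), a small B-box zinc finger protein, from 8.71 to 2.73 FPKM (2.60-fold lower), and AT2G15020 from 36.5 to 15.4 FPKM (2.29-fold lower). The other 7 of the 10 lowest, ERF15, AT2G44940, AT5G57080, AT1G13608, ASG8, AT2G27420 and AT1G76240, were between 1.94-fold and 1.77-fold lower. These genes were taken from protein-coding genes that were above 0 at every exposure and had a locus of at least 300 bp shared with no other listed gene, a restriction chosen after the values were seen. Among all 13946 genes with a mean of at least 5 FPKM, 78 were at least 2-fold higher and 20 at least 2-fold lower at 20 s. Of the 11529 genes in the restricted set, 50 were higher and 3 lower.

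On the genome coordinates of the deposited table (TAIR9, per the submitters' processing notes), PHI-1 lies on chromosome 1 from 12851997 to 12853128, DREB26 on chromosome 1 from 7696536 to 7697699, and NATA1 on chromosome 2 from 16298227 to 16299202. TCH4 lies on chromosome 5 from 23307130 to 23308282, EXO on chromosome 4 from 5740297 to 5741524, and ASN1 on chromosome 3 from 17437884 to 17441243. Each value is for the whole annotated gene and does not separate exons, introns or untranslated regions.

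**Figure D1:**
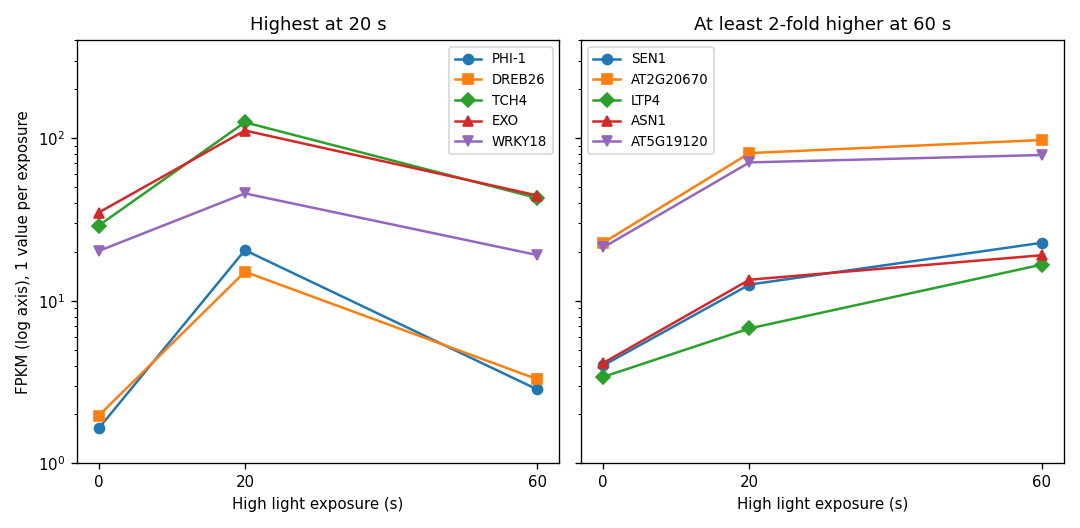
FPKM on a log axis against seconds of high light for the 5 restricted-set genes with the lowest 60 s against 20 s ratio (left) and the 5 with the highest 60 s against 0 s ratio (right), with 1 deposited value per point and no error. TCH4 stood at 29.0, 125 and 42.8 FPKM and SEN1 at 4.01, 12.6 and 22.7 FPKM.

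Gene lists fixed before the data were examined separated into groups at 20 s. Among the rapid stress transcription factors, genes of the WRKY, ZAT, ERF and MYB families known to respond early to stress, 16 of the 18 members with a mean of at least 5 FPKM were higher at 20 s and 2 were lower. WRKY18 went from 20.3 to 45.7 FPKM and MYB44, whose locus overlaps another listed gene, from 28.6 to 59.1 FPKM, while WRKY46 (23.4 and 21.9 FPKM) and MBF1C (15.2 and 13.2 FPKM) were the lowest 2. The median log2 ratio of the list was 0.41, and 0 of 10000 random lists matched on mean FPKM had a median as high. The jasmonate list had 14 members higher and 3 lower with a median of 0.48, which 0 random lists reached. JAZ1, a jasmonate-responsive repressor, went from 5.98 to 11.5 FPKM and VSP1, a vegetative storage protein, stood at 30.3 FPKM (log2 ratio 0.73), against AOS at 108 and 99.9 FPKM. In the list of salicylic acid and defence genes, 12 members were higher and 2 lower (median 0.23, reached by 0 random lists), with the pathogenesis-related genes PR1 at 152 and 264 FPKM and PR2 at 245 and 375 FPKM. Touch and calcium response genes had a median of 0.20, matched or exceeded by 23 random lists, with 6 members higher and 2 lower. TCH4 belongs to that list, and the calmodulin-like TCH2 went from 55.0 to 79.6 FPKM.

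Over the same exposures the summed FPKM of 4 ribosomal RNA genes stood at 136 at 0 s, 1504 at 20 s and 570 at 60 s, so that this measure of RNA makeup was also highest at 20 s, like the lists of stress transcription factors, touch genes and salicylic acid genes. At 20 s the ribosomal RNA genes made up 0.181% of the FPKM sum. How RNA was selected for each library (by poly(A) or by depletion) is not given in the sources used here, and these sums depend on it.

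Abscisic acid and dehydration genes were lower at 20 s on balance, with 10 members lower and 5 higher (median -0.10, with 49 random lists as low). COR15A stood at 77.9 and 52.2 FPKM and KIN2 at 455 and 340 FPKM, whereas RD26, a NAC transcription factor induced by abscisic acid and dehydration, was 2.80-fold higher at 14.8 FPKM. The circadian clock list had 11 members lower and 5 higher (median -0.07, with 197 random lists as low), and its lowest member was FKF1, a blue light photoreceptor, at 10.8 and 6.27 FPKM. Medians of the lists for reactive oxygen species scavenging (-0.01), heat shock (-0.09), light signalling and flavonoid synthesis (-0.01), photosynthesis (-0.04), auxin (0.05), cytosolic ribosomal proteins (0.04) and reference genes (-0.01) lay within the middle 95% of their random lists. In the restricted set the photosynthesis median was -0.07 and lay below that range. About 5% of lists fall outside such a range by chance, and random lists lack the co-regulation of real ones.

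The comparison of 60 s with 0 s asked which transcripts differed after the longer exposure. SEN1 (AT4G35770), a senescence-associated gene that is also dark-inducible, was 4.74-fold higher, at 4.01 FPKM at 0 s and 22.7 FPKM at 60 s. ASN1 was 3.90-fold higher (4.15 against 19.1 FPKM), TPS11 (AT2G18700), a class II trehalose-6-phosphate synthase, was 3.07-fold higher (15.4 against 49.3 FPKM), and AT1G80440, a kelch repeat protein, was 3.32-fold higher (18.6 against 64.0 FPKM). LTP4 (AT5G59310), a lipid transfer protein, was 4.02-fold higher (3.41 against 16.7 FPKM) and RD26 was 3.17-fold higher (4.63 against 16.8 FPKM). AT2G20670 (97.4 FPKM, 4.14-fold), AT5G19120 (78.7 FPKM, log2 ratio 1.84), NATA1 (5.62 FPKM, 3.41-fold) and AT4G27450 (67.9 FPKM, 3.10-fold) completed the 10.

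Lower at 60 s were 4 closely related plant defensin genes whose reads can be shared between copies, so that their separate values are uncertain. PDF1.3 stood at 11.3 and 2.92 FPKM (3.14-fold lower), PDF1.2c at 6.97 and 2.49 FPKM, PDF1.2 at 14.9 and 6.01 FPKM, and PDF1.2b at 6.91 and 2.79 FPKM. AT3G01345 was 3.16-fold lower at 4.86 FPKM, and AT5G36920 was 2.17-fold lower. NIMIN-2, which encodes a protein that binds the salicylic acid regulator NPR1, was 1.98-fold lower, SPX1, a sensor of phosphate status, was 1.82-fold lower, and AT3G44450 and AT5G57080 were 1.83-fold and 1.78-fold lower. In total 75 genes were at least 2-fold higher and 26 at least 2-fold lower at 60 s against 0 s, and 49 and 6 in the restricted set.

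All 17 tested members of the jasmonate list were higher at 60 s than at 0 s (median 0.29, reached by 0 of 10000 random lists). AOC1, an allene oxide cyclase of jasmonate synthesis, went from 13.7 to 28.4 FPKM and JAZ3 from 9.35 to 16.8 FPKM, while OPR3 (33.2 and 35.4 FPKM) and VSP1 (log2 ratio 0.09) differed least. Abscisic acid and dehydration genes had 14 members higher and 1 lower (median 0.21, reached by 1 random list), led by RD26 and by RD20, a caleosin, at 17.2 and 26.7 FPKM. RD22 was the exception at 485 and 477 FPKM. Auxin early response genes were higher in 8 of 8 (median 0.21, reached by 15 random lists), with IAA14 at 8.06 and 13.2 FPKM and IAA1 at 11.6 and 18.4 FPKM. Photosynthesis genes were higher in 24 of 29 (median 0.15, reached by 0 random lists), a count that includes LHCB1.3, which was listed at 0 at 0 s. LHCB1.4, a light-harvesting protein of photosystem II, stood at 2551 and 3323 FPKM, and the lowest ratios in that list were those of LHCB4.3 (76.6 and 54.5 FPKM) and RBCS1B, a Rubisco small subunit (1482 and 1197 FPKM). LHCB copies also share sequence, and their separate values are uncertain.

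The salicylic acid and defence list lay on the other side at 60 s, with 13 members lower and 1 higher (median -0.25, with 0 random lists as low). PBS3, which acts in salicylic acid synthesis, stood at 12.8 and 8.86 FPKM. PDF1.2, a list member usually described as responsive to jasmonate and ethylene, was 2.26-fold lower. Heat shock genes had 6 members lower and 2 higher (median -0.17, with 11 random lists as low), with HSP90.1 at 14.5 and 10.6 FPKM. The stress transcription factors had 10 higher and 8 lower with a median of 0.02, and ERF1A at 5.77 and 8.04 FPKM was their highest member. Within the random range were also the touch list (median -0.05), the clock list (0.07), the light signalling and flavonoid list (-0.06; below the range at -0.09 in the restricted set), the cytosolic ribosomal proteins (-0.07), the reference genes (0.05) and the scavenging list (0.03). In the scavenging list FSD1, an iron superoxide dismutase, was 2.64-fold higher (9.45, 16.7 and 26.6 FPKM at 0, 20 and 60 s) and CAT3, a catalase, stood at 639, 859 and 1057 FPKM. ELIP1, an early light-induced protein, was at 8.56, 8.41 and 4.96 FPKM.

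**Figure D2:**
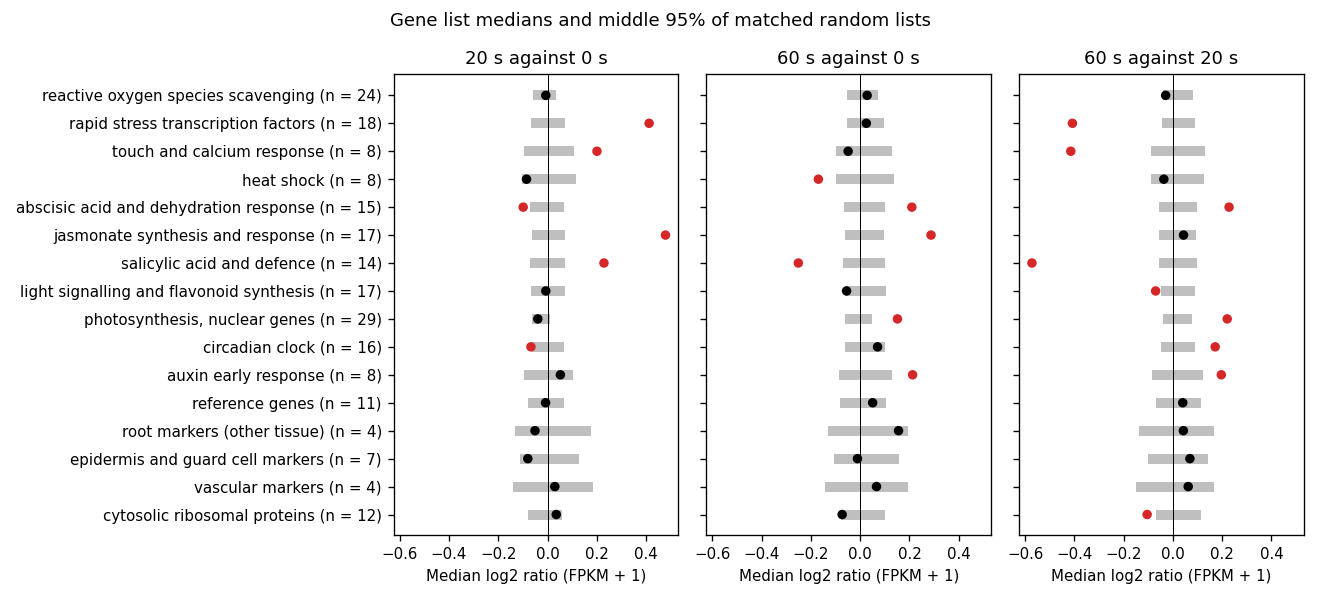
Median log2 ratio of FPKM + 1 for each gene list in the 3 comparisons (points, red where outside the bar), with bars for the middle 95% of 10000 random lists matched on mean FPKM and n as the number of members tested. The stress transcription factor list stood at 0.41, 0.02 and -0.41 and the salicylic acid and defence list at 0.23, -0.25 and -0.57.

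The comparison of 60 s with 20 s asked what differed within the exposure itself. PHI-1 stood at 2.85 FPKM (5.58-fold lower than at 20 s), DREB26 at 3.29 FPKM (3.75-fold lower), TCH4 at 42.8 FPKM (2.88-fold lower), EXO at 44.4 FPKM (2.48-fold lower) and WRKY18 at 19.1 FPKM (2.32-fold lower). Genes picked for a high value at 20 s tend to lie lower at any other time by selection alone. The glycine-rich protein gene AT1G07135 (52.9 and 24.8 FPKM), AT4G26055 and the defensins PDF1.3, PDF1.5 and PDF1.2c were between 2.13-fold and 2.05-fold lower. Higher at 60 s than at 20 s were LTP4 (6.76 and 16.7 FPKM), the glycine-rich protein gene AT2G05540 (67.8 and 150 FPKM), the expansin EXPA8 (40.2 and 88.5 FPKM), AT5G54585 (11.5 and 25.9 FPKM) and AT5G18030, a small auxin-responsive gene (10.5 and 22.5 FPKM). The next 5 were SIS, P5CS1 of proline synthesis (48.4 and 94.4 FPKM), the growth-related PRE1, AT2G15020 and the auxin-responsive AT1G29460, between 1.93-fold and 1.85-fold higher. EXPA8 and PRE1 had been lower at 20 s than at 0 s, at 69.6 and 8.31 FPKM at 0 s. The counts at 2-fold were 20 higher and 33 lower, and 5 and 11 in the restricted set.

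Between 20 s and 60 s the stress transcription factors were lower in 17 of 18 (median -0.41), the salicylic acid and defence genes in 14 of 14 (median -0.57) and the touch genes in 7 of 8 (median -0.41), each with 0 of 10000 random lists as low. Examples were MYB44 at 59.1 and 33.9 FPKM, PR1 at 264 and 149 FPKM and TCH2 at 79.6 and 45.5 FPKM. Abscisic acid genes were higher in 14 of 15 (median 0.23, reached by 0 random lists), with RAB18 at 8.86 and 15.9 FPKM and COR15A at 52.2 and 88.6 FPKM. Photosynthesis genes were higher in 24 of 29 (median 0.22, reached by 0), clock genes in 15 of 16 (median 0.17, reached by 2) and auxin genes in 7 of 8 (median 0.20, reached by 12). Cytosolic ribosomal proteins were lower in 9 of 12 (median -0.10, with 26 random lists as low). The light signalling and flavonoid list had a median of -0.07, with 68 random lists as low, but -0.02 and within the range in the restricted set. Its members went apart, with PIF4 at 28.6 and 40.8 FPKM and DFR, an enzyme of anthocyanin synthesis, at 33.1 and 24.0 FPKM. The jasmonate (0.04), scavenging (-0.03), heat shock (-0.04) and reference gene (0.04) medians were within the range.

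The comparisons of 20 s and of 60 s with 0 s shared 36 genes at least 2-fold higher and 13 at least 2-fold lower, and 0 genes stood 2-fold apart in opposite directions. Independent lists of those sizes would share 0.419 and 0.0373 genes. In the restricted set 20 higher genes (0.213 for independent lists) and 1 lower gene, AT3G01345, were shared. Across those 11529 genes, which are not independent replicates, the log2 ratios correlated at 0.58 with a covariance of 0.0231. Simulated groups with no difference from the same 0 s values gave a correlation of 0.50 and a covariance of 0.00766, with an error taken from the middle of the 60 s against 20 s ratios because none was measured. With equal error in every group and a shared 0 s value, a correlation of 0.50 is fixed in advance. The simulated covariance is likewise set by the assumed error. Neither value therefore tells how much of the observed correlation or covariance comes from the shared 0 s values. At that error the simulation put 0 genes at 2-fold in either comparison, so it gives no chance value for the number of shared genes. With 1 value at 0 s the controls could not be split, and part of the sharing may come from them. Among the 50 genes of the restricted set higher at 20 s, 22 were less than 1.5-fold higher at 60 s and 14 were at least as high at 60 s as at 20 s.

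**Figure D3:**
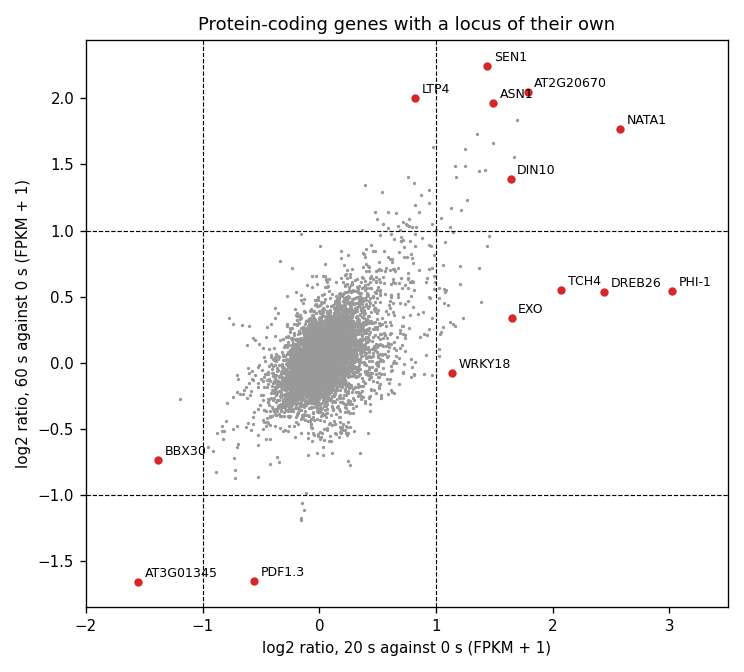
Log2 ratio of FPKM + 1 at 60 s against 0 s (vertical axis) plotted on that at 20 s against 0 s (horizontal axis) for the 11529 genes of the restricted set, with dashed lines at 2-fold and some of the named genes in red. PHI-1 lay at 3.02 and 0.54, and SEN1 at 1.44 and 2.25.

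Markers of other tissues gave a check on the makeup of the shoots. The 6 floral markers stayed under 5 FPKM and were not tested. Of 11 root markers, 4 reached a mean of 5 FPKM, and their median ratios of -0.05 at 20 s and 0.16 at 60 s against 0 s, and 0.04 at 60 s against 20 s, were within the random range. Epidermis and guard cell markers (-0.08, -0.01 and 0.07) and vascular markers (0.03, 0.07 and 0.06) were within it as well. All 7 tested epidermis and guard cell markers were nevertheless lower at 20 s than at 0 s. With 4 root and 4 vascular markers tested, small differences in makeup could not be seen. All 133 chloroplast and 146 mitochondrial genes were listed at 0 at every exposure, so the organelle share could not be measured.

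Without the restriction, the genes with the most extreme ratios were mostly short features listed at 0 at 1 or more exposures, for which no fold is given because a 0 can be a failed estimate. LHCB1.3 (AT1G29930, chromosome 1 from 10478005 to 10479048) was listed at 0 at 0 s and at 15970 and 18990 FPKM at 20 and 60 s, while its neighbours LHCB1.1 and LHCB1.2, with near-identical sequence and chosen after their values were seen, had 3841 and 3562 FPKM at 0 s. AT2G41082, 105 bp long, was listed at 842 FPKM at 0 s and at 0 afterwards. MIR171b was listed at 0, 0 and 119 FPKM, MIR394b at 0, 31.0 and 0 FPKM, and the small nucleolar RNA SNOR30 at 0, 0 and 62.8 FPKM. Of the 31 genes with a mean of at least 5 FPKM that were listed at 0 somewhere, 26 spanned less than 300 bp. Outside the restricted set because of an overlapping locus, and chosen after the values were seen, were AT3G15450 at 94.6, 359 and 423 FPKM and the expansin-like EXLA1, 3.52-fold higher at 20 s (13.2 and 49.0 FPKM) and 1.19-fold higher at 60 s.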

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

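The tests of a difference in the 20 s pools alone and in the 0 s pools alone were chosen after the results were seen, and the single structural RNA genes were named after their values were seen. No pools handled without high light were analysed here, so handling common to the 20 s and 60 s pools is confounded with light in every pattern, including the jasmonate, carbon starvation and iron results. The summed FPKM of structural RNA genes lies outside the gene lists of the report, although single genes of these types enter its 2-fold counts, and some of the sums stood above the 0 s level. Ribosomal RNA genes summed to 1504 FPKM at 20 s and 570 FPKM at 60 s, against 136 FPKM at 0 s, almost all of it from AT3G41768 (136, 1491 and 569 FPKM). Small nuclear RNA genes summed to 160 FPKM at 20 s and 83.4 FPKM at 60 s, against 35.6 FPKM at 0 s, most of it from U1.5 (30.3, 150 and 78.4 FPKM). Small nucleolar RNA genes did not share this order, at 2028, 1542 and 2082 FPKM. These sums depend on how RNA was selected for each library, which is not given in the sources used here.

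Stress transcription factor and jasmonate lists were higher at 20 s. A bias by gene length or GC content is argued against, since both medians stayed above all 10000 random lists matched on mean FPKM, exonic length and GC content (percentile 100 for the lower of the pair). A difference of the 20 s pools alone is argued against for the jasmonate list, whose median at 60 s against 0 s was also at percentile 100. A difference of the 0 s pools alone stays open for the jasmonate list, because its median at 60 s against 20 s was 0.04, at percentile 74.8 and so within the random range. For the stress transcription factor list a difference of the 20 s pools alone stays open, because its median at 60 s against 0 s was at percentile 57.8, and with 1 value per exposure a brief response to light and a feature of the 20 s pools, such as handling or touch, cannot be told apart.

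Among the genes at least 2-fold higher at 20 s and at 60 s were SEN1, ASN1, DIN10 and TPS11, known from carbon-starved tissue. A carbon starvation programme was tested as a hypothesis on a held-out list with none of the genes seen at the top, written before its values were looked at. Its 14 tested members had a median of 0.27 at 60 s and 0.29 at 20 s against 0 s, at percentile 100 among random lists at 60 s, and still at percentile 100 after matching on gene length and GC content, which argues against such a bias. Members of the held-out list can vary together, which random lists lack, and they were read from the same pools as the genes seen first. The percentiles are therefore no independent support for the hypothesis. A difference of the 0 s pools alone stays open, because the list's median at 60 s against 20 s was 0.09, at percentile 95.9 and so within the random range. A real difference reached by 20 s and lower starvation levels in the 0 s pools cannot be told apart from these values.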

How the results depend on the processing

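The restricted set and the 1.5-fold limit were chosen after seeing the data; the other alternatives were fixed before. No list median outside its random range changed sign, and no named gene at 2-fold or more did. Pseudocounts of 0.1 and 0.5, median centring and quantile normalization left every 2-fold count within 1.5 times its main value, and scaling shifted the median of all genes by -0.03 at most. Counts of genes higher and lower moved by more under other settings, mostly because more or fewer genes enter. With any FPKM above 0 they were 122 and 36 at 20 s against 0 s and 42 and 56 at 60 s against 20 s. With a mean of at least 1 FPKM, 32 were lower at 20 s against 0 s and 35 higher at 60 s against 20 s. With a mean of at least 20 FPKM the counts were 44 and 11 (20 s against 0 s), 44 and 9 (60 s against 0 s) and 8 and 13 (60 s against 20 s). In the restricted set they were 50 and 3, 49 and 6, and 5 and 11, with 20 and 1 shared between the comparisons with 0 s. At 1.5-fold they were 249 and 70, 235 and 59, and 76 and 173.

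The number of lists outside the random range stayed within 1.5 times in all 18 repeats. Of list medians, 141 kept their place above, within or below the range, and 3 moved across the edge of the range in the restricted set, as given in the report. The sign of medians within the range was not compared. Median centring shifted the 60 s against 0 s ratios by -0.03. That is as large as the medians there of the stress transcription factor list (0.02) and the scavenging list (0.03), so their direction is open. Of named gene values, 230 kept their side of 2-fold and 10 passed it, those of ERF15, NIMIN-2, SIS and PRE1. No paired analysis was possible because the table has no column per pool. For the same reason the leave-one-out fits, the fit of 6 samples, robust eBayes, camera, fry, and the adjusted p and q settings were not run, nor was the organelle share, since all organelle genes are listed at 0. The unknown depth leaves the counting error of every value unknown.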

Other observations

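The families below, the single genes named with them, bHLH38, AT2G30766 and the genes named for their span were chosen after their values had been seen, and the spans of subsets of genes were compared after the first span test. All 6 tested members of the EXORDIUM family were higher at 20 s than at 0 s and all 6 were lower at 60 s than at 20 s, with a median log2 ratio of 1.01 at 20 s and 0.44 at 60 s against 0 s. Besides PHI-1 and EXO these were EXL3 (72.0, 142 and 91.1 FPKM at 0, 20 and 60 s), EXL5 (33.4, 69.6 and 39.1 FPKM), EXL2 (35.5 and 26.1 FPKM at 20 and 60 s) and EXL4 (5.59, 9.99 and 8.91 FPKM). Of 13 xyloglucan endotransglucosylase/hydrolase genes, 10 were higher at 20 s, among them XTH24 (46.0, 100.3 and 62.6 FPKM) beside TCH4. BTB and TAZ domain genes, known from sugar and nitrate responses, were higher at both times in 4 of 4, with BT2 at 87.1, 208 and 246 FPKM and BT1 at 30.4, 46.1 and 68.3 FPKM. Of 6 class II trehalose-6-phosphate synthase genes, 5 were higher at 20 s and 6 at 60 s, with TPS8 at 30.3, 60.3 and 63.8 FPKM and TPS5 at 11.6, 9.83 and 11.9 FPKM. Scaling the columns moves the median ratio by up to -0.03, which is as large as the 60 s ratios of TPS5 and TPS7 (0.03 for each), so their direction is open.

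Iron deficiency regulators were lower at 20 s, seen first in bHLH38 (86.0, 48.5 and 59.7 FPKM) and the iron-responsive peptide gene AT2G30766 (627, 369 and 404 FPKM). A shared difference of iron deficiency genes was tested on a held-out list of 10 others, written before its values were seen. All 10 were lower at 20 s than at 0 s, with a median of -0.45 at 20 s, at percentile 0 among 10000 matched random lists, and of -0.43 at 60 s, where BHLH101 was the exception at 21.3 FPKM at 0 s and 23.1 FPKM at 60 s. Examples were BHLH39 at 39.6, 25.2 and 28.0 FPKM, IMA1 at 260, 181 and 169 FPKM and PYE at 37.3, 25.6 and 29.1 FPKM. Members of such a list can vary together, which random lists lack, and they were read from the same pools as the genes seen first. The percentile is therefore no independent support. The median at 60 s against 20 s was 0.02. A lower iron deficiency signal in the exposed pools, from light or from handling, or a higher one in the 0 s pools, may lie behind this, and the values do not separate them.

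Genes at least 2-fold higher after 20 s pose a question of speed, since transcripts begun and finished during the exposure would favour short genes. The 50 such genes of the restricted set had a median genomic span of 1527 bp, at percentile 0 among random lists matched on mean FPKM (random median 2314 bp), as that explanation predicts. Because FPKM is scaled by length, a shorter gene at equal FPKM has fewer fragments and a less certain ratio. A 2-fold limit on single values can favour short genes for that reason alone, so the test cannot decide for the explanation. Completion within the exposure would allow longer genes at 60 s than at 20 s. The 29 genes at least 2-fold higher at 60 s but not at 20 s had spans as short (median 1454 bp, percentile 0.02). Short spans were thus not particular to the 20 s genes, although no test of the difference between these sets was made. Of the 50 genes, 17 (34%) span at least 2 kb, against a median of 62% in the random lists. They include BXL1 (4864 bp, 34.8 and 95.1 FPKM), SIP2 (4394 bp, 33.0 and 77.4 FPKM) and ASN1 (3360 bp). Whether transcripts of that length can be completed in the exposure, or whether slower decay or differences between pools are needed, was not tested.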
